A study of Mus musculus with 12 samples.

How the data were processed

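The data are 12 single-cell RNA libraries of male mouse brain, 8 of sorted microglia (5′ kit) and 4 of total brain cells (3′ kit), as the labels give them. The deposited values are raw UMI counts per gene and barcode, written by Cell Ranger 6.0.1 per the file headers. The submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.3.0 and the builds mm10 and GRCm38, without giving their role or order, and how barcodes were chosen is not stated. The sorted files hold 32288 features, of which 3 are reporter sequences (tdTomato, WPRE and their joint transcript), and the brain files hold 32285. GENCODE M21 holds the IDs of 99.6% of the brain features, and coordinates are from it.

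Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Doublets were ranked by scrublet scores in scanpy 1.11.5, and the highest were removed at 0.8% per 1000 barcodes. Scrublet's own threshold marked 0 to 14 cells in the sorted libraries and 134 to 342 in the brain libraries, so the fixed share was used for both. The cells kept were 10415 in sorted sham, 4567 on day 14, 5503 in flox, 9380 in cKO, 869 and 403 in the day 28 ASO-control and ASO-Zfp384 libraries, and 4208 and 2197 in the day 56 ones. In the brain libraries they were 7235 in sham, 4857 on day 14, 6333 with ASO-control and 5198 with ASO-Zfp384. Median UMIs per barcode ran from 4224 to 6523 in sorted and from 4653 to 5264 in brain libraries, and total UMIs per library from 3911469 to 64872263.

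Sorted and brain libraries were clustered apart (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1 with leidenalg 0.10.2 and igraph 0.11.9). Clusters were named from marker lists of 20 classes, written beforehand. A name needed 3 markers present at 100 CPM, a score of 0.5, a gap of 0.75 to the next class and a second score of at most 2. A cluster also stayed unnamed with fewer than 20 cells or with more than 50% of its cells removed as doublets. So did clusters with low UMIs and no own marker among the top 10 genes, or with more markers of another class there. These naming thresholds were set after the clusters were seen and before any groups were compared. Clusters without a name held 1.67% to 14.1% of the cells of a library and were left out of the comparisons. An unnamed sorted cluster led by Spp1 and Gpnmb, with Igf1 and Apoe among its top genes, held 282 day 14 and 26 sham cells. It held 221 cKO and 55 flox cells. A name ending in "-like" means marker expression only.

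Counts were summed over the cells of a class in each library and scaled to CPM by the total of those cells. Each ratio is log2 of first over second CPM, without a pseudocount, and has an exact 95% interval for a ratio of Poisson counts. Shares have exact Clopper-Pearson intervals. These intervals cover counting error only, and a count of 0 allows up to 3 counts. There is 1 library per group, so no test between groups was run, no p-value is given and no paired or batch analysis was possible. Cells are not replicates.

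The design, the gene lists, the rule for naming genes and the alternatives were written before the data were examined. The named genes of a comparison are the 10 in each direction (5 for brain classes other than microglia) with the largest log2 ratio of CPM plus 5, among genes at 50 CPM or more in at least 1 library. Zfp384, Igf1, Spp1 and Cx3cr1 are always given, as are list members used as examples. The 14 microglia lists and 7 brain lists use genes at 10 CPM or more in at least 1 of the libraries compared. A list's median uses CPM plus 5, and its percentile is among 10000 random lists drawn from 20 bins of expression. Of 445 list and marker genes, 2 had no feature. Shares of cells with a UMI use cells thinned to 1000 UMIs. Correlations across genes use genes with a mean of at least 20 CPM, and the day 14 sets the 100 genes with the largest higher ratio. Brain classes were compared where both libraries had at least 50 cells.

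Alternatives were no doublet removal, a stricter filter (1000 UMIs, 5% mitochondrial), a looser one (20% mitochondrial), equal weight for each cell, all cells of a sorted library, TMM (edgeR 4.0.16) and DESeq2 1.42.0 scaling in R 4.3.3, a pseudocount of 1 CPM, list genes without a filter or at 50 CPM, thinning to 2000 UMIs or none, genes at 100 CPM for correlations, correlations without ribosomal protein, mitochondrial and immediate early genes, 50 or 200 day 14 genes, and Leiden resolution 0.5. Resolution 0.5 was used for brain class shares only. Leaving out the cluster led by heat-shock genes was added after the data were seen, as were regional neuron markers and the shuffles of the brain class ratios. The share of 1 sign expected in 3 comparisons was corrected for the share of each sign after it was seen. Intervals and the naming rule were tested on simulated Poisson counts, which checks the calculation and not the spread between cells or animals. Intervals of genes simulated without a change held the true value for 95.0% to 95.9% of genes. Those of genes simulated with a change held it for 90% to 100% of 50 genes in each set. All 10 named genes were genes simulated with a change in each of 6 comparisons. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

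The cKO deletes the part encoding the DNA-binding domain, which gene counts do not resolve, so the deletion was not checked. Reads, splice junctions and RNA velocity were not used here. The reporter features enter only the closing section. Results on genes withheld for evaluation are not reported here.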

Results

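Single-cell RNA was measured in male mice after a transient occlusion of the middle cerebral artery (60 minutes of blocked flow followed by reperfusion, a model of ischaemic stroke) and in sham-operated mice. There were 12 libraries, 1 per group, and the number of animals in each was not stated. In 8 libraries the cells were microglia, the resident macrophages of the brain, sorted as CD45-intermediate and CD11b-intermediate cells. The other 4 libraries held total brain cells. The study asks whether Zfp384, a zinc-finger DNA-binding protein, ends the phase in which microglia make the trophic factor IGF1 after stroke, and whether removing it keeps that phase open. Zfp384 was removed in microglia by Cx3cr1-CreER recombination of a floxed allele (the conditional knockout, cKO), or lowered with an antisense oligonucleotide (ASO), a short synthetic strand that leads to the breakdown of its matching RNA. ASO was given on days 8 and 22 for the day 28 libraries, and on days 29 and 43 for the day 56 libraries.

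Sorted libraries held 53892736 UMIs (unique molecules counted) in sham, 41208879 on day 14, 32316883 in the day 28 flox control and 59529923 in the day 28 cKO. The day 28 ASO libraries were the smallest, with 6925646 UMIs for ASO-control and 3911469 for ASO-Zfp384. The day 56 libraries held 21200515 for ASO-control and 13447072 for ASO-Zfp384. Total brain libraries held 54160182 in sham, 64872263 on day 14, 60331816 for day 28 ASO-control and 50666687 for day 28 ASO-Zfp384. Microglia-like cells, named by their marker genes, numbered 9642, 3862, 4920, 8331, 726, 316, 3595 and 1963 in the 8 sorted libraries in the order above. They numbered 1277, 1179, 3023 and 1718 in brain sham, day 14, day 28 ASO-control and day 28 ASO-Zfp384.

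With 1 library per group no difference between groups could be tested, so differences are described as higher or lower values, and none is shown to exceed the variation between animals. Levels are CPM, the UMI counts of a gene over all microglia-like cells of a library scaled to the same total, and ratios are log2 of the named group over its control. Intervals are exact Poisson or binomial 95% intervals and cover counting error only. Gene lists were fixed before the data were examined. A list member counts as higher or lower when it differs by 1.5-fold or more, and the percentile of a list's median is its place among 10000 random lists of similarly expressed genes.

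The fate of Igf1, Spp1 and Zfp384 across the 12 libraries gives the frame for the comparisons. Igf1 (ENSMUSG00000020053, GRCm38 chromosome 10, 87858265 to 87937042) encodes a growth factor for neurons, oligodendrocytes and vessels. It was at 1.04 CPM (0.765 to 1.39) in sorted sham microglia and 283 CPM (277 to 288) on day 14. On day 28 it was at 39.4 CPM in the flox control and 73.1 CPM in the ASO-control, and on day 56 at 26.0 CPM in the ASO-control. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) encodes osteopontin, a secreted matrix protein of phagocytic microglia. It was at 5.83 CPM in sham, 3937 on day 14, 259 and 192 in the day 28 flox and ASO controls, and 119 in the day 56 ASO-control. Zfp384 (ENSMUSG00000038346, chromosome 6, 125009145 to 125037870) was at 40.5 CPM (38.6 to 42.4) in sham and 49.9 (47.6 to 52.3) on day 14. It was at 56.1, 49.7 and 46.7 CPM in the day 28 flox, day 28 ASO and day 56 ASO controls. These values are of sorted cells. In brain microglia-like cells Igf1 was at 1.80 CPM in sham, 368 on day 14 and 276 in the day 28 ASO-control, so the sorted fall by day 28 was not matched there. Spp1 was at 0.601, 3795 and 1328 CPM in the same brain libraries, and Zfp384 at 17.1, 14.6 and 15.9. Weighting every cell equally instead of by its UMIs lowered sorted Igf1 to 183 CPM on day 14, 25.5 in the flox control and 15.9 in the day 56 ASO-control.

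**Figure D1:**
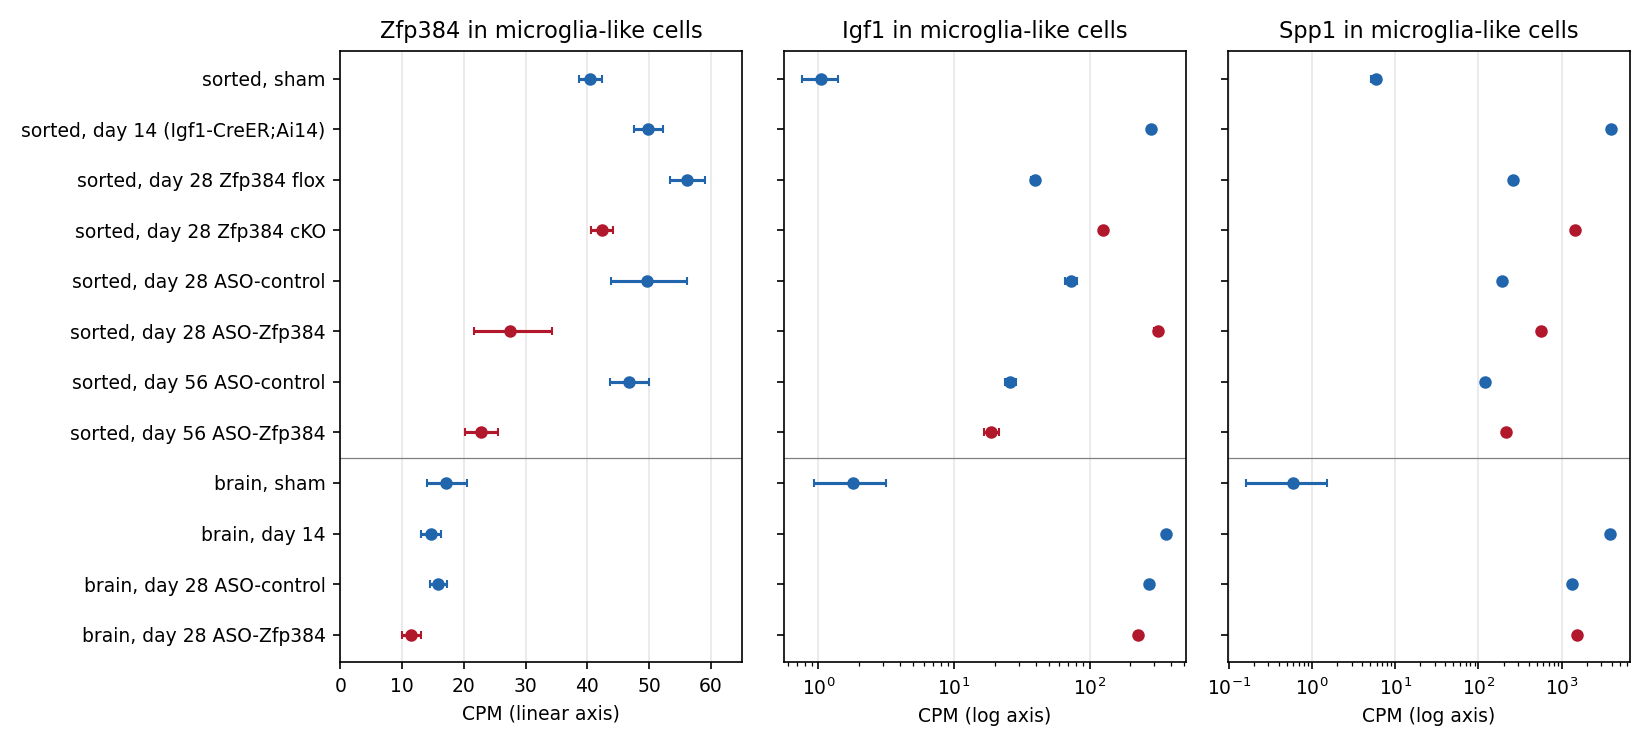
CPM of Zfp384 (linear axis), Igf1 and Spp1 (log axes) in microglia-like cells of each of the 12 libraries, with 95% Poisson intervals and the cKO and ASO-Zfp384 libraries in red. Igf1 lies at 1.04 CPM in sorted sham, 283 on day 14 and 26.0 in the day 56 ASO-control.

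The share of microglia-like cells with an Igf1 UMI, with each cell thinned to 1000 UMIs, was 0.0626% in sorted sham, 12.3% (11.3 to 13.4) on day 14, 1.84% in the flox control, 3.60% in the day 28 ASO-control (26 of 722 cells) and 1.27% in the day 56 ASO-control. As background, 2 of 57 endothelial-like cells of the day 14 library carried one (3.51%; interval 0.428 to 12.1; median 7367 UMIs, against 6157 in its microglia-like cells). In the day 28 flox control it was 0 of 18 endothelial-like cells, which allows up to 16.7% (median 5716 UMIs against 5062). In the day 28 ASO-control it was 1 of 37 endothelial-like cells (2.70%; interval 0.0684 to 14.2; median 16774 UMIs against 6259.5). In the day 28 and day 56 ASO-control libraries no UMI was seen in 13 neutrophil-like cells each, which allows up to 23.1%. The few non-microglial cells of the sorted libraries therefore cannot exclude a background of the size of these shares after stroke. Spp1 UMIs were in 25.5% of day 14 microglia-like cells, beside 19.3% of those 57 endothelial-like cells.

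Sorted microglia on day 14 were compared with sham. The day 14 library comes from Igf1-CreER;Ai14 reporter mice and sham from wild-type mice, so surgery and genotype differ together and the injury alone is not separated. On day 14 the microglia carried the lipid-handling and phagocytic program described around demyelination and neurodegeneration: the lipoproteins Apoe and Apoc1, the fatty-acid carrier Fabp5, the lipoprotein lipase Lpl, the protease inhibitor Cst7 and the membrane protein Gpnmb were far above sham. Fn1, encoding the matrix protein fibronectin, and Cd72, an inhibitory surface lectin, were higher too. Genes of the resting state were lower, among them the purinergic receptor P2ry12, Tmem119, Selplg and Crybb1. Interferon-response genes were higher throughout.

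In values, Spp1 stood at a log2 ratio of 9.40 (9.22 to 9.58), Igf1 at 8.08 (7.66 to 8.53), Apoe at 6.46 (26623 against 303 CPM), Fabp5 at 6.54, Cst7 at 6.20, Lpl at 5.10, Cd72 at 4.89 and Apoc1 at 9.56. Gpnmb had 1 count in sham, a ratio of 12.22 (9.74 to 17.53), and Fn1 had 3 counts, a ratio of 10.96 (9.42 to 13.24). Among the genes with the largest lower values were the sulfotransferase Sult1a1 (-1.88), the membrane protein Tmem204 (-2.06), the RNA-binding protein Khdrbs3 (-1.90), the mTOR-restraining stress gene Ddit4 (-1.73), Crybb1 (-1.59), the platelet glycoprotein gene Gp9 (-1.73), the adaptor Bank1 (-1.69), the phosphatase Dusp7 (-1.60), Ccnb1ip1 (-1.65) and Upk1b (-1.56). Zfp384 was slightly higher, at 0.30 (0.20 to 0.40), and Cx3cr1 lower, at -0.46.

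The phagocytic disease-associated list had a median of 2.55 (percentile 100), with 19 of 22 measured genes higher and 0 lower, Axl at 4.92 and Itgax at 3.58 among them. The groups lay in different clusters, with the Spp1-led one holding 28.9% of day 14 and 0.0726% of sham cells. The interferon list had a median of 2.43, 18 of 18 higher, including Ifi27l2a (4.20), Oasl2 (3.83) and Ifitm3 (3.59). The homeostatic list had a median of -0.60 (percentile 0), with 10 of 20 lower, including P2ry12 (-1.31; 1798 against 4460 CPM), Selplg (-1.26), Tmem119 (-1.20) and Fscn1 (-1.28). Antigen presentation had a median of 1.22 with 7 of 12 higher, including Cd74 (2.24) and H2-D1 (2.10). In the same cells border macrophage markers summed to 22.5 CPM on day 14 and 5.54 in sham, and monocyte markers to 15.4 and 5.36, so other myeloid cells are not excluded as a part of such values. Mrc1, a leading gene of border macrophage-like cells in the brain libraries, was lower, at 2.11 and 3.68 CPM. Ccr2 was at 1.43 and 1.25 CPM. Cell cycle had a median of 1.05 with 10 of 14 higher, including Mki67 (2.91; 26.6 against 3.54 CPM) and Top2a (2.49). Lipid uptake and efflux had a median of 0.95 with 12 of 13 higher. The inflammatory list was mixed, with a median of 0.55, 9 of 19 higher and 1 lower: Cxcl2 (4.77), Il1rn (4.60), Cxcl10 (2.75), Ccl5 (2.71) and Il1b (2.12) were higher, Il6 (-1.85) lower.

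Trophic factors had a median of 0.70 with 5 of 9 higher, glycolysis 0.61 with 8 of 15 higher (Hif1a 1.92, Eno1 1.76), and the lysosome 0.55 with 10 of 20 higher (Ctsb 1.51, Cd63 1.46). Oxidative phosphorylation (0.05), cholesterol synthesis (-0.08) and immediate early genes (-0.28) had medians near 0. Transcription and chromatin-loop regulators had a median of -0.14, with Bhlhe40 higher (5.42) and Maf lower (-0.92). The median of all genes was -0.17 on the CPM scale, -0.06 after TMM and -0.05 after DESeq2 scaling. The cholesterol median became 0.01 and 0.02 under those scalings, and oxidative phosphorylation became -0.04 with cells weighted equally.

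Microglia-like cells of the total brain libraries give a separate day 14 to sham comparison, between wild-type animals, without a sort and with a different library kit. The same program led: Spp1, Cst7, Lpl, Apoc1, Apoe, Igf1 and the galectin Lgals3 were far above sham, and so was the interferon gene Ifi27l2a. The T-cell chemokine Ccl5 was higher as well, but T or NK cell markers in the same cells summed to 11.3 CPM on day 14 and 0.150 in sham, so it is not assigned to microglia. Border macrophage markers summed to 70.6 and 29.1 CPM and monocyte markers to 46.5 and 25.1, so the class II genes below are not assigned to microglia alone. Mrc1, which led the border macrophage-like cluster, went the other way, at 5.59 and 20.9 CPM. Ccr2, among the top genes of the monocyte-like cluster, was at 4.09 and 4.95. The sums alone therefore do not show more of these cells. Homeostatic genes were lower by more than in sorted cells. The lowest ratios belonged to the heat-shock genes Hspa1a and Hspa1b and to neuronal transcripts such as Snap25, Nrgn and Cck, which microglia do not make.

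Spp1 stood at 12.63 (11.27 to 14.50; 3795 CPM against 4 counts in sham), Igf1 at 7.67 (368 against 1.80 CPM), Cst7 at 8.57, Lpl at 7.46, Apoe at 5.92, Ccl5 at 8.68, Ifi27l2a at 5.39 and Lgals3 at 5.34. Apoc1 had 2 counts in sham, a ratio of 10.18 (8.33 to 13.22). Gpnmb had 0 counts in sham and 211 CPM on day 14. Igf1 UMIs were in 22.1% of day 14 microglia-like cells (19.8 to 24.6) and in 0.274% of endothelial-like cells (median 12685 and 3647.5 UMIs). In sham the shares were 0.157% and 0.312% (4964 and 3166 UMIs). The heat-shock genes Hspa1b (-6.40) and Hspa1a (-5.17) and the neuronal transcripts Snap25 (-4.68; 9.78 against 251 CPM), Nrgn (-4.12), Cck (-4.51), Stmn3 (-4.15), Vsnl1 (-4.66) and Npy (-4.76) were lower, beside Khdrbs3 (-4.12) and Bank1 (-4.27).

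The phagocytic list had a median of 3.22 (percentile 100, 21 of 22 higher, 0 lower) and the homeostatic list -1.34 (percentile 0, 17 of 20 lower, 0 higher), with Crybb1 at -2.61, Slc2a5 at -2.47 and P2ry12 at -2.14. The groups lay in different clusters: those led by Ccl4 and by Apoc1 held 52.8% and 25.2% of the day 14 cells and 0.157% and 0.0783% of the sham cells. Interferon genes had a median of 2.78 (19 of 19 higher, with Irf7 4.64), antigen presentation 1.96 (9 of 13 higher, with H2-Aa 5.96, Cd74 3.98), lipid handling 1.39 (13 of 14 higher), and the inflammatory list 1.41 (12 of 19 higher, 5 lower, with Cxcl2 3.48, Ptgs2 4.04, Ccl4 among the lower). The lysosome had a median of 0.77 (11 of 20 higher, 2 lower, with Cd63 2.41), trophic factors 0.61 (6 of 12 higher, 2 lower, with Hbegf -2.44) and glycolysis 0.57. Cholesterol synthesis had a median of -0.46 (percentile 22.6, 3 of 10 lower, with Idi1 -1.67), or -0.07 after TMM scaling, and no direction is given. Cell cycle had a median of 1.34 (8 of 13 higher, with Mki67 3.75), but -0.22 over its members above 50 CPM.

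Here the scaling mattered. The median of all genes was -0.34 on the CPM scale, 0.11 after TMM and 0.09 after DESeq2 scaling. Cx3cr1 was -0.45 on the CPM scale, 0.06 after TMM and 0.04 after DESeq2 scaling; Zfp384 was -0.23 (-0.54 to 0.10), 0.28 and 0.27. Oxidative phosphorylation went from -0.10 to 0.39 and 0.38, and the regulator list from -0.46 to 0.02 and 0.00. Immediate early genes went from -0.50 to 0.01 after TMM. No direction is given for these. Neuronal RNA also differed between the libraries, so the lower neuronal transcripts go with the material and not with the cells alone. Over all genes, sorted and brain day 14 ratios correlated with a Pearson r of 0.773 across 6246 genes.

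In the day 28 cKO against the flox control, the question is what microglia express without Zfp384. In sorted controls of this time Igf1 was far below the sorted day 14 level, which was not so in the brain libraries. Microglia of the cKO had higher levels of day 14 genes, among them Spp1, Gpnmb, Lgals3, Igf1, Lpl and Apoe. Interferon genes, with the chemokine Cxcl10, Ifit2, Isg15 and Ifi27l2a, were higher, and inflammatory genes such as Ccl2 and Tnf were higher as well. Ddit4, the serine-synthesis enzyme Phgdh, the translocon protein Tram1 and Cx3cr1 were lower. The knockout carries the Cx3cr1-CreER allele, which takes the place of Cx3cr1 itself, and the flox control is labelled with no such allele. Loss of Zfp384 and the driver are therefore not separated for Cx3cr1 or for any other gene of this comparison.

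Spp1 stood at 2.47 (2.43 to 2.50; 1433 against 259 CPM), Gpnmb at 2.28, the hexose transporter Slc2a6 at 2.21, Cxcl10 at 1.82, Ifit2 at 1.82, Lgals3 at 1.76, Igf1 at 1.66 (1.57 to 1.76; 125 against 39.4 CPM), Isg15 at 1.56, Ifi27l2a at 1.54 and Cd72 at 1.54. Ddit4 stood at -2.33, Phgdh at -1.88, the glutathione-processing enzyme Ggt5 at -1.76, Tram1 at -1.68, Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879) at -1.51 (1070 against 3047 CPM), Bank1 at -1.25, Rnaset2a at -1.17, the cyclooxygenase Ptgs1 at -0.97, Tuba1b at -0.96 and Fam110a at -0.96. Zfp384 itself stood at -0.41 (-0.50 to -0.31; 42.3 against 56.1 CPM). The recombined allele lacks the DNA-binding domain, and transcripts of the rest of the gene are still counted, so this value does not measure the loss. The share of cells with an Igf1 UMI was 6.39% (5.87 to 6.94) against 1.84% (1.48 to 2.25), beside 2 of 22 endothelial-like cells in the cKO (9.09%; median 7564 UMIs against 4950.5), which does not separate it from background.

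The phagocytic list had a median of 0.86 (percentile 100, 16 of 22 higher, 0 lower, with Lpl 1.33, Fabp5 1.24, Apoe 1.05; the Spp1-led cluster held 9.13% of cells against 3.23%) and the homeostatic list -0.34 (percentile 0, 2 of 20 lower, 0 higher), with Csf1r (-0.58) following Cx3cr1. Interferon genes had a median of 1.13 (17 of 18 higher, with Rsad2 2.61), antigen presentation 0.39 (3 of 12 higher, with H2-D1 1.09, B2m 0.80), lipid handling 0.30 (4 of 13 higher) and the inflammatory list 0.42 (6 of 18 higher, 1 lower, with Cxcl2 1.97, Ccl2 1.29, Tnf 1.26). Border macrophage markers in these cells summed to 13.2 CPM in the cKO and 5.61 in the flox control, while Mrc1 alone was at 0.614 and 2.31 CPM. Cell cycle had a median of 0.21 over 6 measured genes (percentile 99.9, 0 past 1.5-fold), while Mki67 was at 5.65 against 2.07 CPM. Medians were small but high among random lists for trophic factors (0.15, percentile 99.9), glycolysis (0.14, 100), lysosome (0.11, 98.6) and oxidative phosphorylation (0.08, 99.7). Cholesterol synthesis (-0.07) and regulators (-0.12; Bhlhe40 1.73) lay near 0. Immediate early genes had a median of 0.21 (5 of 20 higher, with Nr4a1 1.46). Heat-shock genes Hspa1a and Hspa1b together stood at 762 CPM in the cKO and 453 in the flox control, so the libraries also differ in a sign of handling.

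For the ASO given from day 8, sorted microglia on day 28 address whether lowering Zfp384 keeps the level of Igf1 up. The low control level was seen in sorted cells. The brain ASO-control on the same schedule was at 276 CPM, against 368 in brain on day 14. Igf1, Lpl, Cst7, Apoe, Apoc1, Fabp5 and the receptor tyrosine kinase Axl were higher with ASO-Zfp384, led by Baiap2l2, a membrane-bending adaptor. Ank and the chemokine Ccl6 were higher too. Homeostatic receptors such as P2ry12, P2ry13 and Gpr34 were lower, and so were Upk1b, Ggt5, Ddit4 and the inhibitory receptors Clec4a2 and Siglece. These are the smallest libraries, with 316 and 726 microglia-like cells.

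Zfp384 stood at -0.86 (-1.24 to -0.48; 27.5 against 49.7 CPM), Igf1 at 2.12 (1.94 to 2.29; 317 against 73.1 CPM), Spp1 at 1.54, Cx3cr1 at -0.35, Baiap2l2 at 2.95 (2.60 to 3.31), Lpl at 2.37, Cst7 at 2.10, Apoe at 2.003 (32426 against 8090 CPM), Axl at 1.92, Ank at 1.71, Apoc1 at 1.71, Ccl6 at 1.63 and Fabp5 at 1.62. The potassium channel gene Kcnk12 stood at -1.98, Serpinf1 at -1.53, Upk1b at -1.47, the ferritin pseudogene Ftl1-ps1 at -1.46, Ggt5 at -1.26, Lst1 at -1.23, Ddit4 at -1.15, Siglece at -1.10, Clec4a2 at -1.08 and Klk8 at -1.08. Igf1 UMIs were in 14.0% of cells (10.4 to 18.4) against 3.60% (2.37 to 5.23), beside 2 of 31 endothelial-like cells (6.45%; interval 0.791 to 21.4; median 21893 UMIs against 6549) and 0 of 11 neutrophil-like cells.

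The phagocytic list had a median of 1.39 (percentile 100, 15 of 22 higher, 0 lower), which was 0.66 when all cells of each library were summed, and the homeostatic list -0.35 (percentile 0, 5 of 20 lower, with P2ry12 -0.95, P2ry13 -0.87). The Spp1-led cluster held 20.6% of cells against 3.03% and the Apoe-led one 25.9% against 9.37%. Interferon genes had a median of 0.86 (13 of 16 higher, with Oasl2 1.41, Ifi27l2a 1.40), cell cycle 0.83 (10 of 15 higher, with Cdk1 1.95, Mki67 1.73), antigen presentation 0.59 (7 of 13 higher, with H2-Eb1 2.70, Cd74 1.37) and lipid handling 0.56 (6 of 13 higher). The inflammatory list had a median of 0.13 (1 of 20 higher, 2 lower, with Il1rn 2.77, Il6 -0.96, Il1a -0.66). Medians were small but high among random lists for the lysosome (0.25, percentile 100, 0 of 20 past 1.5-fold) and trophic factors (0.19, percentile 99.7). Cholesterol synthesis (0.07), glycolysis (0.02), oxidative phosphorylation (0.02) and regulators (-0.15; Bhlhe40 1.52, Zfp143 -0.67) lay near 0. Immediate early genes were at -0.08, and 0.04 over all cells.

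The ASO given from day 29 and read on day 56 had both a later start and a later reading than the day 28 libraries. A later start alone is therefore not separated from the time after stroke. Igf1 was not higher. Among genes at 50 CPM or more, most of the largest higher values were interferon genes: Ifi27l2a, Ifitm3, Irf7, Ifit3, Rtp4 and Oas1a, the class I gene H2-Q7 and the galectin-binding Lgals3bp. Genes of dividing cells, Stmn1 and the histone Hist1h2ap, were with them, and cell cycle genes below that level had larger ratios. Spp1 and Axl were higher, while Igf1, Apoe, Apoc1 and Gpnmb were lower.

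Zfp384 stood at -1.04 (-1.24 to -0.84; 22.7 against 46.7 CPM) and Igf1 at -0.46 (-0.70 to -0.24; 18.9 against 26.0 CPM), or -0.22 with cells weighted equally. Spp1 stood at 0.85, Cx3cr1 at -0.35, Ifi27l2a at 3.35 (3.26 to 3.44; 621 against 60.9 CPM), Irf7 at 2.64, Ifitm3 at 2.55, Stmn1 at 2.55, Ifit3 at 2.22, Hist1h2ap at 2.19, Oas1a at 2.04, H2-Q7 at 2.002, Rtp4 at 1.91 and Lgals3bp at 1.65. Zfp62 stood at -1.01, Strn3 at -0.88, the depalmitoylase Abhd17c at -0.87, Bank1 at -0.77, Zkscan3 at -0.76, Zfp871 at -0.70, Slc9a9 at -0.69, Csmd3 at -0.63, Glrx3 at -0.62 and the cytokine Osm at -0.62. Cells with an Igf1 UMI made up 1.28% against 1.27%, with no difference detectable at this depth. Haemoglobin genes summed to 0.242 CPM against 213 CPM, so blood RNA differed between these libraries. Mki67 UMIs were in 24 of 1955 cells (1.23%; 0.788 to 1.82) against 1 of 3541 (0.0282%).

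The cell cycle list had a median of 1.92 (percentile 100, 14 of 17 higher, 0 lower, with Mki67 5.82, Top2a 5.07, Birc5 4.57), and the interferon list 1.62 (16 of 16 higher). The interferon-led cluster held 208 cells against 52 in the control and the dividing cluster 103 against 5, so part of these values lies in small groups of cells. The phagocytic list had a median of 0.19 (percentile 100, 2 of 22 higher, 1 lower, with Axl 1.25, Gpnmb -1.06), which was 0.10 over all cells, and the homeostatic list -0.18 (percentile 0.02, 0 of 20 past 1.5-fold; P2ry13 -0.49, Gpr34 -0.45). The inflammatory list had a median of 0.24 (5 of 18 higher, with Cxcl2 2.80, Cxcl10 1.47, Ccl12 0.96), while monocyte markers in these cells summed to 17.3 against 6.43 CPM. Ccr2 alone went the other way, at 0.484 against 1.46 CPM. The list member Ccl5 stood at 2.72 in microglia-like cells and at -0.29 over all cells, so no direction is given for it. The lysosome list had a median of 0.24 (percentile 100, 1 of 20 higher; Grn 0.59). The other medians were 0.18 for oxidative phosphorylation, 0.11 for antigen presentation (H2-D1 0.92), 0.09 for glycolysis, 0.06 for lipid handling (Apoc1 -0.91), 0.02 for cholesterol synthesis, -0.03 for trophic factors, -0.12 for regulators (Mef2c -0.32) and -0.16 for immediate early genes (Nr4a1 -1.41).

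**Figure D2:**
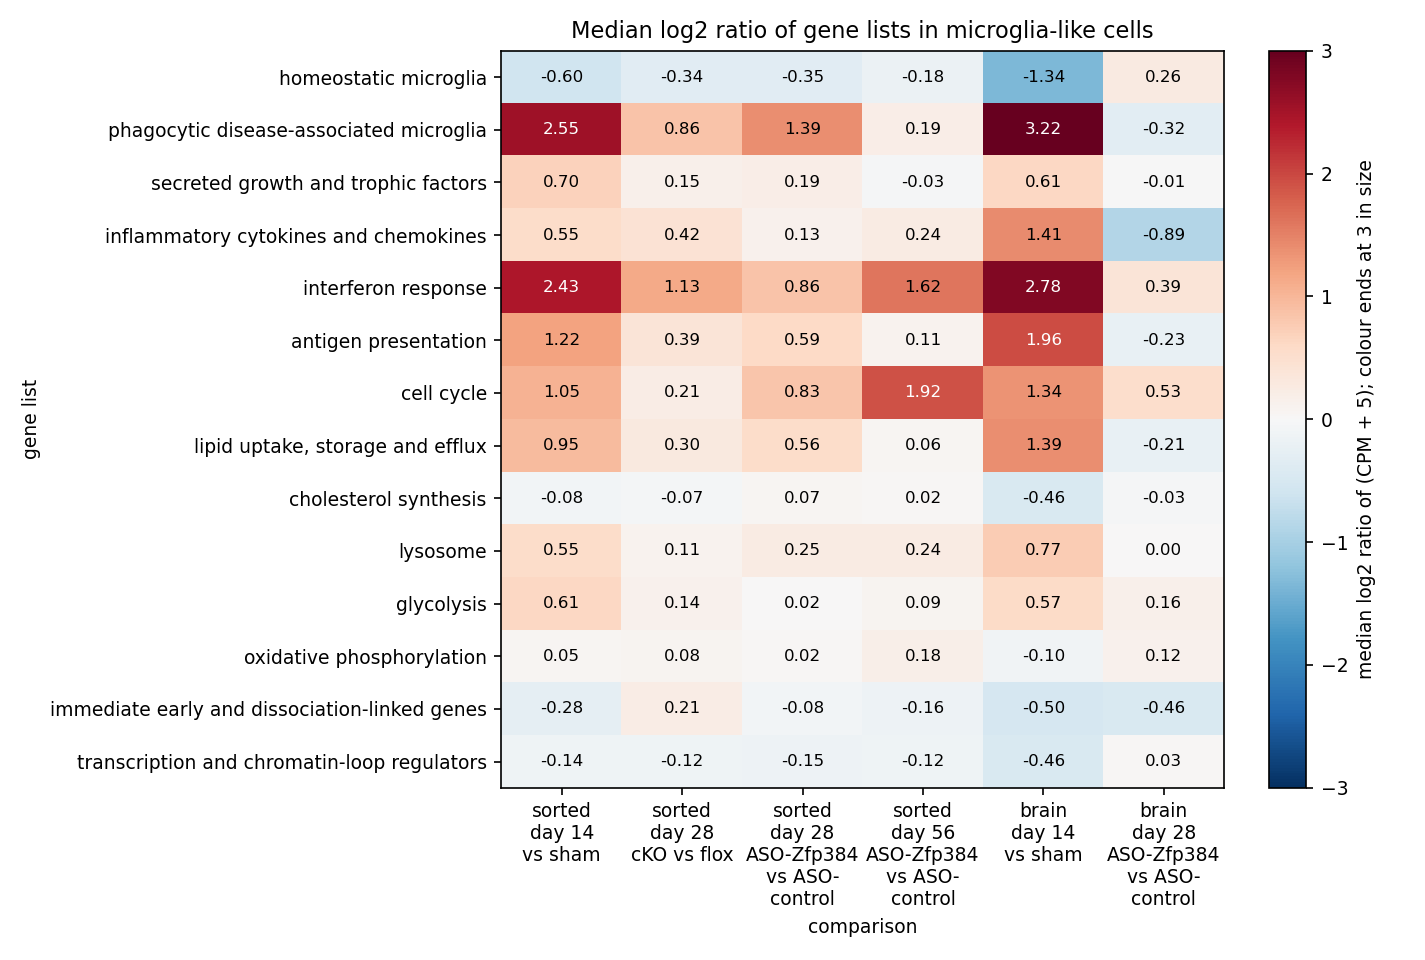
Median log2 ratio of each of the 14 gene lists in microglia-like cells for the 6 comparisons, with colour ending at 3 in either direction. The phagocytic list is at 0.86 in the cKO, 1.39 and 0.19 with ASO-Zfp384 on days 28 and 56 in sorted cells, and -0.32 in total brain.

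Total brain cells on day 28 had the same ASO schedule as the sorted day 28 cells, and ask what the ASO does across cell types. In brain microglia-like cells the acute-phase gene Saa3, the glucocorticoid-response gene Fkbp5, the scavenger receptor Stab1 and the resting-state genes Crybb1, Lst1 and Tmem119 were higher with ASO-Zfp384. Genes of inflammatory activation were lower: the chemokines Cxcl2 and Ccl3, the cytokine Il1b, the adhesion molecule Icam1, the stress gene Gadd45b and the class II genes H2-Eb1 and Cd74. Igf1 was slightly lower. Oligodendrocyte markers in these cells summed to 209 CPM with ASO-Zfp384 and 396 with ASO-control, so RNA of other cells differed too. The immediate early genes Fos and Dusp1 were also lower in each of 7 other brain classes, with medians of -0.73 and -0.72. A difference in handling between the libraries is therefore not excluded for the lower inflammatory genes.

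Zfp384 stood at -0.47 (-0.71 to -0.24; 11.4 against 15.9 CPM), Igf1 at -0.29 (-0.34 to -0.24; 226 against 276 CPM), Spp1 at 0.21 and Cx3cr1 at -0.08. Saa3 stood at 3.40 (3.17 to 3.64), Fkbp5 at 1.27, Camk2n1 at 1.25, the linker histone Hist1h1d at 1.08, Stab1 at 1.04, Ifi27l2a at 1.03, Crybb1 at 1.00, Lst1 at 0.94, Tmem119 at 0.90 and Alox5ap at 0.77. Cxcl2 stood at -2.21 (47.7 against 221 CPM), Gadd45b at -1.79, the niacin receptor Hcar2 at -1.55, H2-Eb1 at -1.51, Il1b at -1.27, Csrnp1 at -1.26, Cd74 at -1.13, Irf1 at -1.13, Icam1 at -1.11 and Ccl3 at -1.06. Igf1 UMIs were in 12.2% of cells (10.7 to 13.9) against 16.9% (15.6 to 18.3), with 0 of 329 and 1 of 360 in endothelial-like cells (median 9604 and 9091 UMIs in microglia-like cells, 3912 and 3534 in endothelial-like cells).

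The inflammatory list had a median of -0.89 (percentile 0, 11 of 18 lower, 0 higher, with Ccl4 -1.03), immediate early genes -0.46 (6 of 19 lower, with Atf3 -0.88, Fos -0.77), the phagocytic list -0.32 (percentile 0, 6 of 22 lower, 0 higher, with Itgax -0.89, Lpl -0.87, Lgals3 -0.72), antigen presentation -0.23 (4 of 14 lower, with H2-Aa -1.12) and lipid handling -0.21 (2 of 14 lower, with Apoc1 -0.94). The homeostatic list had a median of 0.26 (percentile 100, 3 of 20 higher, 0 lower, with Ltc4s 0.65, P2ry12 0.54). Cell cycle had a median of 0.53 (5 of 12 higher, with Birc5 1.504, Top2a 0.94) and interferon genes 0.39 (5 of 18 higher, with Rtp4 0.97, Irf7 0.83). Glycolysis (0.16), oxidative phosphorylation (0.12), regulators (0.03; Maf 0.54), lysosome (0.00), trophic factors (-0.01) and cholesterol synthesis (-0.03) lay near 0. The clusters that held the microglia differed: 1314 of the 3023 ASO-control cells lay in an inflammatory cluster marked by Ccl4, Ccl3 and Tnf, against 329 of 1718 with ASO-Zfp384.

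Side by side, the 3 sorted losses of Zfp384 (cKO, ASO on day 28, ASO on day 56) shared single genes above and below their controls, interferon genes among them. In the cKO the loss goes together with the driver allele. Ifi27l2a (1.54, 1.40 and 3.35), Ifitm3 (1.25, 1.29 and 2.55), the class I gene H2-Q7 (1.501, 1.53 and 2.002), Slc2a6 (2.21, 1.55 and 2.26) and Cd72 (1.54, 1.49 and 1.46) were higher in each. Bank1 (-1.25, -1.54 and -0.77), the kinase Matk (-0.61, -0.62 and -0.60), Gp9 (-0.54, -0.67 and -0.54), the deubiquitinase Usp21 (-0.81, -1.03 and -0.50) and the corepressor Cbfa2t3 (-0.56, -0.80 and -0.52) were lower in each. Igf1 was higher in the cKO and the day 28 ASO library and lower in the day 56 ASO library.

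Across 6247 genes, which are not independent replicates, the log2 ratios correlated with a Pearson r of 0.507 (Spearman 0.395) between cKO and day 28 ASO, 0.405 (0.332) between cKO and day 56 ASO and 0.408 (0.355) between the ASO time points, among 15 pairs computed. All 3 had the same sign for 47.4% of genes, where independent signs with the same share of each sign give 29.9%. Each also correlated with day 14 against sham, at 0.637 for the cKO, 0.621 for the day 28 ASO and 0.458 for the day 56 ASO. The brain ASO comparison correlated at -0.156, -0.215 and 0.221 with the cKO, day 28 ASO and day 56 ASO.

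A set of 100 genes higher on day 14, taken from the brain libraries so that it shares no cells with the sorted ones, had a median of 0.73 in the cKO (61 of 98 genes at least 1.5-fold higher, 0 lower), 0.86 in the day 28 ASO library (62 of 98 higher, 1 lower) and 0.48 in the day 56 ASO library (41 of 88 higher, 2 lower), each at percentile 100. With the 50 highest genes the medians were 1.07, 1.18 and 0.82, and with 200 they were 0.41, 0.49 and 0.30. The set's median in sorted day 14 against sham was 2.20. The matching set from sorted day 14 cells had a median of -0.11 in the brain ASO comparison (percentile 0, 6 of 100 higher, 18 lower).

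Cell classes of the total brain libraries show which cells were present. Astrocyte-like cells made up 31.0% of sham and 7.31% of day 14 cells, neuron-like cells 25.9% and 3.66%, and microglia-like cells 17.7% and 24.3%. Endothelial-like cells were 4.66% and 15.9%, and T or NK cell-like cells 0% (0 of 7235 cells, which allows up to 0.0415%) and 2.35%. An unnamed cluster led by the T-cell gene Cd3g, which scored for both microglia and T or NK cells, held a further 5.70% of day 14 cells (277 cells). Monocyte-like cells were 0.0415% and 1.61%, and neuroblast-like cells, which express Dcx and Sox11, 0.0138% and 5.50%. With ASO-Zfp384 on day 28, microglia-like cells were 33.1% against 47.7% with ASO-control, monocyte-like cells 7.10% against 1.41%, neutrophil-like cells 2.37% against 0.553% and B cell-like cells 4.04% against 1.89%. At a clustering resolution of 0.5 no cluster was named monocyte-like, so that class and its genes depend on the resolution. Oligodendrocyte-like cells were 7.12% against 6.05%, but 11.6% against 12.7% when cells with up to 20% mitochondrial UMIs were kept. Shares come from dissociated tissue of 1 library each, and a smaller share of one class raises all others.

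**Figure D3:**
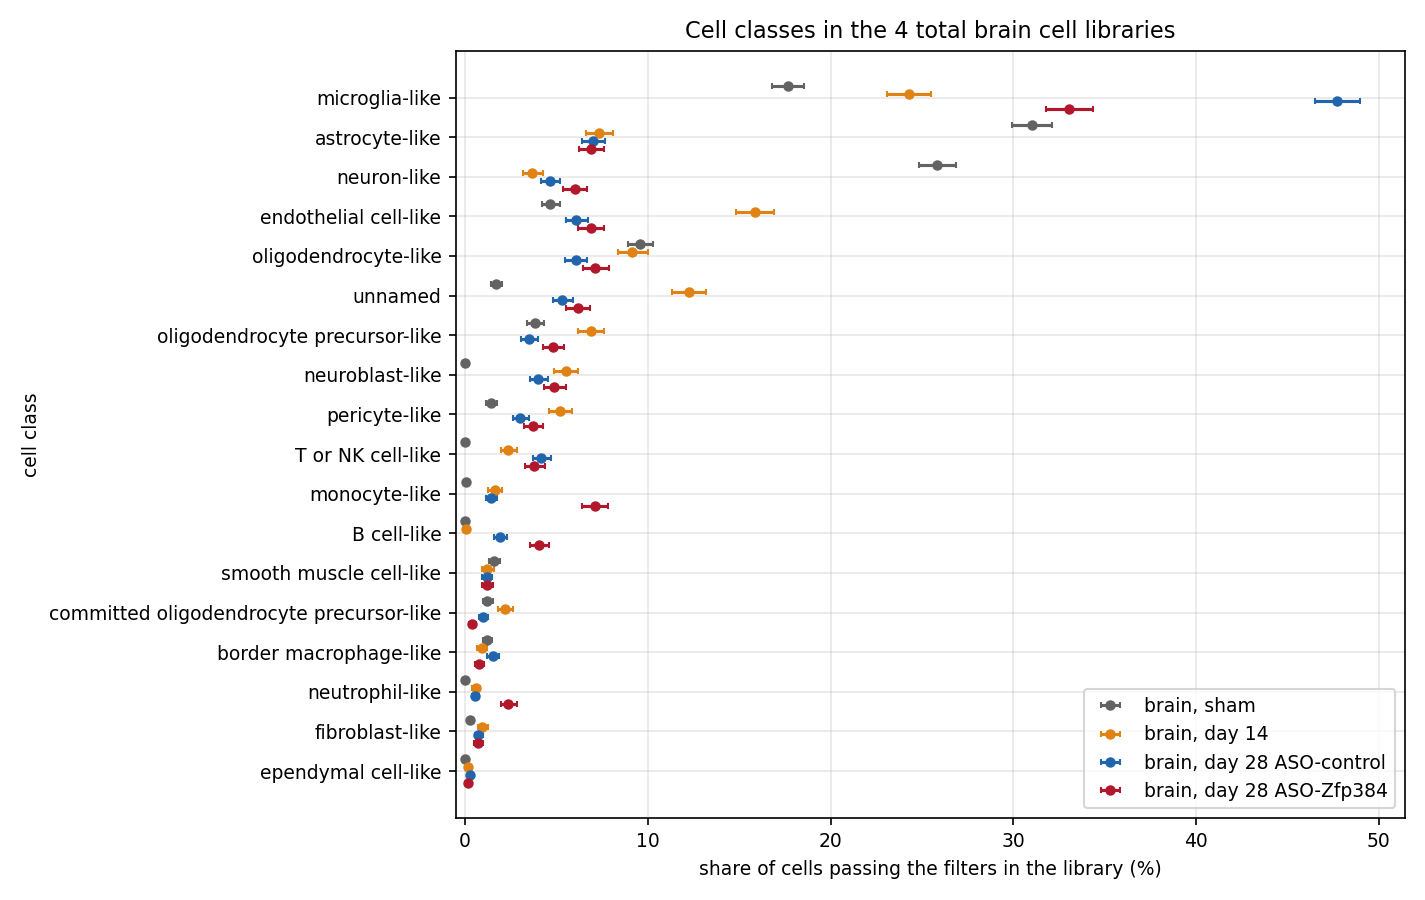
Share (%) of all cells kept in each of the 4 total brain libraries that falls in each named cell class or is unnamed, with 95% binomial intervals. Monocyte-like cells are 7.10% with ASO-Zfp384 and 1.41% with ASO-control, and neuron-like cells 25.9% in sham and 3.66% on day 14.

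On day 14 the glia of the brain libraries carried reactive genes. Astrocyte-like cells carried more Gfap, Vim, Serpina3n, the complement gene C4b and the matrix gene Thbs4, and oligodendrocyte-like cells carried more Serpina3n, C4b and class I genes, the state described as disease-associated oligodendrocytes. The reactive astrocyte list had a median of 3.33 (23 of 23 higher), with Serpina3n at 7.87, C4b at 6.35, Vim at 6.25, Gfap at 6.06 and Thbs4 at 9.51 (355 cells on day 14, 2244 in sham). Of these cells, 229 on day 14 and 1 in sham lay in a single Gfap-led cluster. The homeostatic astrocyte list had a median of -0.60 (6 of 12 lower, 1 higher, with Slc7a10 -1.75, Aqp4 1.97). The disease-associated oligodendrocyte list had a median of 3.64 (10 of 10 higher, with Serpina3n 9.23, C4b 8.26, B2m 5.38), and the myelin list -0.08 (3 of 15 lower, 1 higher, with Mal -1.15, Ermn 0.70). These cells too lay in different clusters, with 93.2% of day 14 and 43.6% of sham cells in a single one. Endothelial activation genes had a median of 1.32 (6 of 10 higher, 1 lower, with Vcam1 2.03) and blood-brain barrier genes 0.23 (1 of 10 higher, with Abcb1a 0.79). Oligodendrocyte precursor-like cells had higher C4b (5.57) and Ifitm3 (6.16). The median of all genes was -0.11 on the CPM scale and 0.09 after TMM scaling in endothelial-like cells, and the barrier median was 0.45 after TMM. Neuronal Snap25 was lower in astrocyte-like (-3.92), oligodendrocyte-like (-3.94), endothelial-like (-3.57) and pericyte-like (-3.39) cells, as it was in microglia. Neuron-like cells had lower Vip (-4.56) and Pvalb (-6.53; 3 counts on day 14, interval -8.81 to -4.98), with a neuronal injury median of 0.22 (3 of 10 higher, 3 lower). The kinds of neuron differed, with the Vip cluster at 7.30% of day 14 and 12.1% of sham neuron-like cells and the Nrgn cluster at 29.2% and 12.4%, so these values are not changes within a kind of neuron.

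With ASO-Zfp384 on day 28, astrocyte-like cells carried more of the reactive genes, as did oligodendrocyte precursor-like and neuroblast-like cells. The Gfap-led cluster held 10.6% of astrocyte-like cells with ASO-Zfp384 and 5.19% with ASO-control. Monocyte-like cells carried more of the arginase Arg1, the chemokines Ccl2 and Ccl7 and the haem oxygenase Hmox1. T or NK cell-like cells carried more Il17a and the gamma-delta T-cell genes Cd163l1 and Tcrg-C1. That class pools kinds of cells. A different mix within it, or within the monocyte-like class, was not separated from changes within cells. Endothelial-like cells carried more Lcn2, Ch25h and Lrg1. Oligodendrocyte-like cells carried more of the glucocorticoid-response gene Sgk1 and the cell-cycle inhibitor Cdkn1a. An ASO is not restricted to microglia, so these differences need not start in them.

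Arg1 stood at 7.52 (6.59 to 8.64; 2305 against 12.6 CPM), Hmox1 at 4.46, Ccl2 at 4.05 and Gpr34 at -2.42 in monocyte-like cells (369 and 89 cells), and Ccl7 at 6.94 (5.08 to 9.99) with 2 counts in the control. Il17a stood at 5.09, Cd163l1 at 3.26 and Tcrg-C1 at 2.79 in T or NK cell-like cells, with Ccl1 at -4.46 (-6.76 to -2.87; 3 counts). The reactive astrocyte list had a median of 1.24 (18 of 20 higher, 0 lower, with Timp1 4.16, Ptx3 3.90, Cd44 2.48, Serpina3n 2.23; 358 and 443 cells), or 1.88 under a stricter cell filter. The same list was at 1.06 in oligodendrocyte precursor-like, 1.02 in neuroblast-like, 0.42 in pericyte-like and 0.30 in endothelial-like cells, so it is not particular to astrocytes. Homeostatic astrocyte genes had a median of 0.08 (0 of 12 past 1.5-fold). Endothelial activation genes had a median of 0.54 (6 of 12 higher, with Lcn2 2.34, Ch25h 2.22, Lrg1 2.08) and blood-brain barrier genes -0.04. Oligodendrocyte precursor-like cells had higher Ifi27l2a (3.24) and Serpina3n (2.97) and lower S100a8 (-5.21). In oligodendrocyte-like cells Sgk1 (2.54) and Cdkn1a (2.59) were higher, Edil3 (-2.53) was lower, and the myelin list had a median of -0.30 (1 of 15 lower, with Opalin -0.65). Classes that do not make myelin had lower medians of that list, at -0.89 in astrocyte-like, -0.89 in endothelial-like, -0.79 in pericyte-like and -0.60 in neuron-like cells, so the value is not assigned to oligodendrocytes and no direction is given for them. The disease-associated oligodendrocyte median was 0.12 (2 of 10 higher, 2 lower, with H2-D1 -0.83) and -0.09 under the stricter filter. In neuron-like cells the injury list had a median of 0.20 (1 of 11 higher, 2 lower) and Nr4a2 stood at 2.42. The neuropeptide genes Nts and Gal turned with the filter or weighting, at 1.26 and -0.32 for Nts and -1.91 and 1.10 for Gal, so no direction is given for them.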

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

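The tests of weaker lowering of Zfp384 in the brain library and of reporter levels relative to the day 14 library were chosen only after the result was seen, as was the list of results set side by side here. The pair of sorted day 56 and brain day 28 was left out of that list after it was seen, because both time and preparation differ. Differences between preparations (sorted and brain) and between times were not tested, since each rests on single libraries.

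With ASO-Zfp384 on day 28, values went in opposite directions in sorted microglia and in brain microglia-like cells. Igf1 was at 2.12 in sorted and -0.29 in brain cells, the homeostatic list at -0.35 and 0.26, the phagocytic list at 1.39 and -0.32, the inflammatory list at 0.13 and -0.89, antigen presentation at 0.59 and -0.23, and lipid handling at 0.56 and -0.21. Igf1 also differed in direction between times, at 2.12 on day 28 and -0.46 on day 56 in sorted cells. The start of the ASO and the day of reading differ together there, and so do the reporter reads described below. The oxidative phosphorylation list on day 14 was at 0.049 in sorted and -0.10 in brain cells, both close to 0 and both dependent on scaling or weighting.

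For the opposite direction of the phagocytic list, a first technical explanation is the share of brain cells in the inflammatory cluster led by Ccl3, Ccl4 and Tnf. Without that cluster the brain median was still negative, at -0.24, which argues against that cluster alone as the whole cause. The shares of the remaining clusters still differed. The P2ry12-led cluster held 655 of 1389 remaining cells with ASO-Zfp384 and 462 of 1709 with ASO-control. A wider shift in cluster shares is therefore not excluded. A weaker lowering of Zfp384 in brain would alone bring the median toward 0 and not below it, and it was at -0.32. That value is the pattern itself, so this test could not come out otherwise. Weaker lowering as a part of the cause is not excluded. Within single brain clusters the medians were 0.06, -0.00, -0.15, -0.18 and -0.27. The clusters were drawn from the same expression values, so smaller medians within them can follow by construction and decide nothing. What also stays open is the animals, the library kit, the sort, and the small sorted libraries, none of which the design separates from the preparation. A biological cause is only an untested possibility.

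Reads of the reporter transcript, which the report does not use, came up in libraries where the labels give no reporter. There were 2304 UMIs in the sorted day 14 library, which is labelled as the reporter line, and 459 and 249 UMIs in the day 28 ASO-control and ASO-Zfp384 libraries, which are labelled wild-type. The share of barcodes with one was 28.3%, 32.5% and 32.1%, and the other 5 sorted libraries had 0 UMIs. Carry-over of reads from the day 14 library would place reporter UMIs in its barcodes, and at most 0.871% were there, which argues against it. The reporter level relative to day 14 was 1.19 in ASO-control and 1.14 in ASO-Zfp384, consistent with animals that carried the reporter allele.

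Whether Igf1-driven recombination lay behind these reads stays open. Cells with an Igf1 UMI had a reporter UMI 0.525 times as often as cells without one in ASO-control and 1.05 times in ASO-Zfp384. A value near 1 was written beforehand as speaking against such recombination, but that bound was wrong: the day 14 library, labelled as that line, itself gave 1.02. That the test decides nothing was concluded only after its result was seen. The reporter was at 81.3 CPM in endothelial-like and 65.7 in microglia-like cells of ASO-control, and at 116 (92.4 to 145) and 53.5 (45.3 to 62.8) in those of ASO-Zfp384, and no biological explanation was tested. If both libraries share the line, their comparison is not affected, but comparing them with the flox, cKO or day 56 libraries adds a genotype.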

How the results depend on the processing

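The alternative without the heat-shock cluster was chosen only after the result was seen, and the others were planned. Counting class shares and shares of cells with an Igf1 UMI among the main results was decided after their values were seen. No paired analysis was possible because each group has 1 library and animals are not named. Over 852 results and 5663 alternatives, 4306 values stayed within the counting interval of the reported value, 1340 lay outside it with the same direction or no called direction, and 17 changed sign. Values below are those of the main results that lay outside their interval and all 17 that changed sign. List values are medians, and the comparison or library is in brackets. Except where shown, the cause was not tested.

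The direction of Igf1, the phagocytic list and the homeostatic list held in all 6 microglia comparisons under every alternative run. The direction of Zfp384 held in 5, and in brain day 14, where its interval included 0, it was positive after scaling. Leiden resolution 0.5 was run for the brain class shares only, and the microglia-like shares of the 4 brain libraries stayed within their intervals. Ratios, gene lists and correlations were not recomputed at that resolution. List genes without a filter left every main result with a value within its interval. So did correlations without ribosomal protein, mitochondrial and immediate early genes. At resolution 0.5 no cluster was named monocyte-like or border macrophage-like, so these shares had no value, and unnamed cells were 653 with ASO-Zfp384 (320 at resolution 1) and 441 with ASO-control (337).

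With every cell weighted equally, Igf1 was 7.66 (sorted day 14), -0.22 (day 56 ASO) and -0.39 (brain ASO), and Zfp384 was 0.45 (sorted day 14). The homeostatic list was -0.43 (sorted day 14), -0.24 (cKO), -0.28 (day 28 ASO), -0.12 (day 56 ASO) and -1.14 (brain day 14), and the phagocytic list was 2.24 (sorted day 14), 0.77 (cKO), 1.2 (day 28 ASO), 0.26 (day 56 ASO), 2.98 (brain day 14) and -0.36 (brain ASO). Oxidative phosphorylation changed sign to -0.038 (sorted day 14), and reactive astrocyte genes were 3.11 (brain day 14). Myelin genes were -0.011 (brain day 14) and -0.22 (brain ASO), and Gal changed sign to 1.10 (brain ASO). Igf1 in CPM was 183 (sorted day 14), 25.5 (flox), 58.6 (day 28 ASO-control) and 15.9 (day 56 ASO-control), and the day 14 set was 0.76 (day 28 ASO) and -0.14 (brain ASO). Over all cells of a sorted library, the homeostatic list was -0.62 (sorted day 14), -0.36 (cKO) and -0.44 (day 28 ASO), and the phagocytic list was 0.88 (cKO), 0.66 (day 28 ASO) and 0.099 (day 56 ASO). Igf1 was 1.79 (day 28 ASO), and immediate early genes changed sign to 0.036 (day 28 ASO). Ccl5 changed sign to -0.29 (day 56 ASO), and Igf1 in CPM was 289 (sorted day 14) and 42.7 (flox). The day 14 set was 0.66 (day 28 ASO) and 0.42 (day 56 ASO).

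After TMM scaling, Zfp384 was 0.42 (sorted day 14), -0.29 (cKO) and 0.28 (brain day 14), and the homeostatic list was -0.48 (sorted day 14), -0.22 (cKO), -0.29 (day 28 ASO), -0.21 (day 56 ASO), -0.83 (brain day 14) and 0.16 (brain ASO). The phagocytic list was 2.64 (sorted day 14), 0.97 (cKO), 3.62 (brain day 14) and -0.42 (brain ASO), and cholesterol synthesis changed sign to 0.014 (sorted day 14). Igf1 was 1.78 (cKO) and -0.39 (brain ASO), and Cx3cr1 changed sign to 0.057 (brain day 14). Oxidative phosphorylation changed sign to 0.39 (brain day 14), and immediate early genes changed sign to 0.0094 (brain day 14). Regulators changed sign to 0.018 (brain day 14), and myelin genes were -0.11 (brain day 14) and -0.37 (brain ASO). Barrier genes were 0.45 (brain day 14), and the day 14 set was 0.83 (cKO), 0.92 (day 28 ASO), 0.46 (day 56 ASO) and -0.21 (brain ASO). After DESeq2 scaling, Zfp384 was 0.43 (sorted day 14), -0.31 (cKO) and 0.27 (brain day 14), and the homeostatic list was -0.47 (sorted day 14), -0.24 (cKO), -0.28 (day 28 ASO), -0.85 (brain day 14) and 0.17 (brain ASO). The phagocytic list was 2.65 (sorted day 14), 0.96 (cKO), 3.61 (brain day 14) and -0.41 (brain ASO), and cholesterol synthesis changed sign to 0.021 (sorted day 14). Igf1 was 1.76 (cKO) and -0.38 (brain ASO), and Cx3cr1 changed sign to 0.041 (brain day 14). Oxidative phosphorylation changed sign to 0.38 (brain day 14), and regulators changed sign to 0.0020 (brain day 14). Myelin genes were -0.13 (brain day 14) and -0.37 (brain ASO), and barrier genes were 0.38 (brain day 14). The day 14 set was 0.81 (cKO), 0.92 (day 28 ASO) and -0.20 (brain ASO).

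With a pseudocount of 1 CPM, the phagocytic list was 2.94 (sorted day 14), and reactive astrocyte genes were 4.79 (brain day 14). Without the heat-shock cluster, the homeostatic list was -0.36 (cKO), and the phagocytic list was 0.92 (cKO). The day 14 set was 0.77 (cKO). With list genes at 50 CPM or more, the phagocytic list was 1.05 (cKO) and 0.26 (day 56 ASO), and cell cycle changed sign to -0.22 (brain day 14). Reactive astrocyte genes were 3.98 (brain day 14). Under the stricter cell filter, the phagocytic list was -0.29 (brain ASO), and reactive astrocyte genes were 1.88 (brain ASO). Myelin genes were -0.23 (brain day 14) and -0.27 (brain ASO), and disease-associated oligodendrocyte genes changed sign to -0.090 (brain ASO). Barrier genes were 0.27 (brain day 14), and Nts changed sign to -0.32 (brain ASO). Bdnf changed sign to -0.018 (brain ASO). Under the looser mitochondrial filter, reactive astrocyte genes were 3.16 (brain day 14) and 1.02 (brain ASO), and myelin genes were -0.020 (brain day 14) and -0.25 (brain ASO). Without doublet removal, barrier genes were 0.30 (brain day 14) and -0.096 (brain ASO), and the microglia-like share was 31.3% (brain ASO-Zfp384), 45.7% (brain ASO-control) and 16.4% (brain sham).

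Without thinning, the share of cells with Igf1 was 0.384% (sorted sham), 35.0% (sorted day 14), 7.95% (flox), 19.6% (cKO), 11.2% (day 28 ASO-control), 41.5% (day 28 ASO-Zfp384), 5.51% (day 56 ASO-control), 5.40% (day 56 ASO-Zfp384), 50.9% (brain ASO-control), 37.8% (brain ASO-Zfp384), 0.783% (brain sham) and 61.2% (brain day 14). Thinned to 2000 UMIs, the share of cells with Igf1 was 19.4% (sorted day 14), 3.11% (flox), 10.7% (cKO), 22.2% (day 28 ASO-Zfp384), 2.52% (day 56 ASO-control), 2.16% (day 56 ASO-Zfp384), 27.0% (brain ASO-control), 19.3% (brain ASO-Zfp384), 0.630% (brain sham) and 33.0% (brain day 14). Over genes at 100 CPM or more, Pearson's r was 0.603 (cKO with day 28 ASO), 0.477 (cKO with day 56 ASO) and 0.497 (day 28 ASO with day 56 ASO), and the share of genes with 1 sign in all 3 losses was 54.6%. With 50 genes, the day 14 set was 1.07 (cKO), 1.18 (day 28 ASO), 0.82 (day 56 ASO) and -0.17 (brain ASO). With 200 genes, the day 14 set was 0.41 (cKO), 0.49 (day 28 ASO), 0.30 (day 56 ASO) and -0.077 (brain ASO). With up to 20% mitochondrial UMIs allowed, the microglia-like share was 21.8% (brain day 14), 27.7% (brain ASO-Zfp384), 40.1% (brain ASO-control) and 15.4% (brain sham), and the monocyte-like share was 5.95% (brain ASO-Zfp384).

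Shares of cells with Igf1 follow depth by construction, and in the day 56 ASO libraries their order turned with thinning. Sets of 50 or 200 genes take stronger or weaker genes by construction. Depth limits the sorted day 28 ASO comparison, with 316 and 726 microglia-like cells, the smaller brain classes, and genes with few counts in sham, whose ratios have wide intervals.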

Other observations

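The values in this part were set side by side after they were seen, except for the tests on the gene set of the brain classes, whose shuffles, comparison with brain microglia-like cells, test of Zfp384 in other classes and limit of the knockout test to microglia-like cells were also chosen only after the result was seen. Microglia of the day 28 and day 56 controls were not at the level of sham. Apoe was at 303 CPM in sorted sham, 11106 in the flox control and 6538 in the day 56 ASO-control, and Cst7 at 11.7, 351 and 141 CPM, while Igf1 was at 1.04, 39.4 and 26.0 CPM. Ddit4, an mTOR-restraining stress gene, and Ggt5 were both among the lowest genes in the cKO (-2.33 and -1.76) and with ASO-Zfp384 on day 28 (-1.15 and -1.26). Bhlhe40, a repressor of lipid-handling microglia, was higher on day 14 (5.42), in the cKO (1.73) and with ASO-Zfp384 on day 28 (1.52).

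Dividing microglia on day 56 are a small group. Mki67 was at 30.6 CPM with ASO-Zfp384 and 0.54 in its control, with 10 counts in the control.

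Neurons of the brain libraries differ in region. Striatal marker genes summed to 444 and 575 CPM in neuron-like cells of sham and day 14 and to 1791 and 2469 CPM in ASO-control and ASO-Zfp384. Excitatory cortical and hippocampal genes summed to 1084, 1268, 579 and 733 CPM. These markers were chosen after the neuron clusters were seen.

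In 7 brain classes other than microglia, 19 of 3258 genes were lower with ASO-Zfp384 in every class with a median of -0.5 or below, and 5 were higher by the same rule. In 1000 shuffles of the ratios between genes of similar level, at most 1 gene met the rule in either direction. The set includes myelin genes (Mag, Mbp, Mobp, Opalin) and microglial genes (C1qa, C1qb, C1qc, Tyrobp), and free RNA was not tested as their source. It also holds the immediate early genes Fos and Dusp1, for which handling was not tested. Strn3 (ENSMUSG00000020954, chromosome 12, 51609632 to 51691897), singled out after its values were seen, was at -3.13 in oligodendrocyte-like, -2.13 in neuron-like, -1.31 in astrocyte-like and -1.16 in microglia-like cells, and in sorted cells at -0.21 in the cKO, -0.74 with ASO on day 28 and -0.88 on day 56. It was also lower on day 14 than in sham, at -0.30 in sorted and -0.78 in brain cells. The other 18 genes of the set were lower in brain microglia-like cells as well, with a median of -0.48 (17 measured, 6 lower by 1.5-fold). In sorted cells 11 or 12 of them were measured, with medians of 0.035 in the cKO, 0.18 with ASO on day 28 and 0.033 on day 56, and the genes measured in the cKO were at -0.26 in brain microglia-like cells. For the measured genes as a set, the cKO values argue against loss of Zfp384 as the cause in microglia-like cells only if the deletion took place. The deletion was not checked and goes with the driver allele, and the sort and library kit differ. The values say nothing of the other classes. The argument does not hold for each gene. Zfp329 went the other way, at -0.44 (-0.62 to -0.26) in the cKO and -1.29 with ASO on day 56. On day 28 Zfp329 was at 0.04. A rule tried first was that the same genes reach -0.25 in brain microglia-like cells. Asked of the genes of all sorted comparisons, it would have left both tests open, since those measured on day 28 were at -0.24. Asked of the knockout genes alone, at -0.26, it would have been met. The sorted ASO values are consistent with a difference between the animals of the brain libraries. In the classes other than microglia Zfp384 stood at -0.58 (-0.88 to -0.28) over the 7 classes summed and was not lower in each, so its loss there stays open, and so does the preparation.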
